A study of Homo sapiens with 6 samples.

How the data were processed

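Cultured, untreated H82 and H524 cells were profiled. Per the labels' protocols, nuclei were sonicated, protein-DNA complexes were recovered with an antibody, and libraries were made with a TruSeq ChIP kit and sequenced on an Illumina NovaSeq. Per the labels, the antibodies were against NeuroD1 and H3K4me3, and each line also had an input library without antibody. The submitters' processing notes name bcl2fastq 1.8.4, Trimmomatic 0.38, Bowtie 1.1.2, SAMtools 1.9, Picard 1.118, MACS2 2.1.1, ChIPseeker 1.18.0 and R 3.5.1 and the genome build hg19, without stating the role or order of each. Trimming, alignment and peak calling settings, duplicate handling, and whether the input libraries served as controls in peak calling are not given in the sources used here. The input libraries were not analysed here. Where peak calling used no matched input, differences in copy number and in mappability between lines would enter the lists, and more reads would lengthen a list.

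Each of the 4 lists holds 1 library, and each has 5 columns with chromosome, start, end, name and score. The score deposited by the authors was read as a −log10 adjusted p-value (q-value) from the values, since the lowest was 1.304 in H82 and H524 NeuroD1, close to the 1.301 that corresponds to 0.05; no header states the unit. Regions with several summits appear once per summit, so entries with the same interval were merged into 1 distinct region with the highest score. This reduced 4137 entries to 3854 regions for H82 NeuroD1, 26319 to 18208 for H82 H3K4me3, 23818 to 20593 for H524 NeuroD1 and 24306 to 18595 for H524 H3K4me3. Coordinates are given 1-based in hg19. Reads per library are not given in the files, so the lists could not be adjusted for depth.

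Samples were grouped by the cell line and antibody in the labels. Regions overlapped when they shared at least 1 bp, counted with bedtools 2.31.1 under Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Each share has an exact Clopper-Pearson 95% interval, and differences between shares have Newcombe intervals. Regions are not independent draws and the lists come from 1 library per group, so the intervals describe counting error within these lists. Overlap by position was set against 1000 random placements of the regions on their own chromosome, between the first and last region of any list, which includes stretches without regions, and against 1000 placements moved by 20 to 200 kb. Distances and width classes used 100 placements. Score classes divided each NeuroD1 list into 10 by its own ranks. The overlap procedure was tested on simulated data built from the real lists. Planted overlaps of 40.0%, 39.7% and 20.0% were recovered as 40.0%, 39.7% and 20.0% for NeuroD1 between lines, H3K4me3 between lines and NeuroD1 on H3K4me3 in H82, and unrelated lists gave 0.950-fold, 1.10-fold and 1.00-fold of random placement over 20 draws. The planted regions were slightly moved copies, so their recovery checked only the counting. The unrelated lists were placed at random, unlike the clustered regions of the real lists.

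The main comparisons, the alternatives and the rule for named regions were fixed before the data were examined, except where a later choice is stated. The plan did not list shares per chromosome and their correlation, distances to H3K4me3, or NeuroD1 on the mark of the other line. It also did not list NeuroD1 on shared against single-line H3K4me3 regions, width classes of H3K4me3 regions, or blocks of 1 Mb. The rule named the 10 highest-scoring regions of each NeuroD1 list, the 10 shared NeuroD1 regions with the highest smaller percentile of both lists, the 5 highest-scoring NeuroD1 regions of each line alone, and the 5 highest-scoring H3K4me3 regions of each line alone that touch a promoter window. The last condition needs a gene annotation and could not be applied, so all H3K4me3 regions of 1 line were eligible. The highest-scoring H3K4me3 regions regardless of sharing were added later. Named genes, classes of genomic annotation, gene lists and E-box content were also planned, but a genome sequence and gene annotation in hg19 were not used here, and regions are therefore named by coordinates without gene context. The alternatives changed the overlap rule, the score threshold, the list lengths, the region width, the chromosomes and the number of score classes.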

Results

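The series profiled NeuroD1 and H3K4me3 by chromatin immunoprecipitation sequencing in the untreated human small cell lung cancer cell lines H82 and H524. NeuroD1 is a neurogenic basic helix-loop-helix transcription factor that binds E-box motifs, and H3K4me3 is a histone mark found at active promoters. The 6 libraries comprised 1 NeuroD1, 1 H3K4me3 and 1 input library per line, and the 4 peak lists of the immunoprecipitated libraries were compared. With 1 library per antibody and line there were no replicates, so no difference could be set against a spread between replicates and no p-value is given. Shares are given with exact Clopper-Pearson 95% intervals, which cover counting error only. The number of reads per library was not given in the files, so the depth behind each list is unknown.

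The NeuroD1 list of H524 was 5.34-fold longer than that of H82, whereas the H3K4me3 lists of both lines were close in length. NeuroD1 was listed at 3854 distinct regions in H82, which covered 1886 kb, and at 20593 regions in H524, which covered 11904 kb. H3K4me3 was listed at 18208 regions over 14970 kb in H82 and at 18595 regions over 12934 kb in H524. The median region width under NeuroD1 was 416 bp in H82 and 470 bp in H524, and under H3K4me3 it was 563 bp and 526 bp. Regions with several summits made up 5.71% and 12.1% of the NeuroD1 lists of H82 and H524, and 22.4% and 19.7% of the H3K4me3 lists. The authors' scores, on a −log10 scale, had medians of 3.61 and 4.04 for NeuroD1 and of 3.59 and 3.60 for H3K4me3. The highest NeuroD1 score was 166 in H82 and 1048 in H524. Scores were used only to rank regions inside a list.

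The first comparison asked how far NeuroD1 occupied the same regions in both lines. More than 1 in 2 of the H82 NeuroD1 regions overlapped a NeuroD1 region of H524, namely 2066 of 3854 (53.6%, 95% interval 52.0 to 55.2). The much longer H524 list had 2055 of its 20593 regions in H82 (9.98%, 9.57 to 10.4). Placing the H82 regions at random on their own chromosomes gave a mean overlap of 0.877% over 1000 placements, 61.1-fold below the observed share. When the regions were instead moved by only 20 to 200 kb, the observed share was 33.1-fold higher than the mean of the placements. With both lists limited to their 3854 highest-scoring regions, the shared part was 22.1% of the H82 regions and 21.7% of the H524 regions.

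The highest-scoring NeuroD1 regions of both lines lay on chromosome 8. From 128 to 129 Mb, the median percentile by score of NeuroD1 regions was 92.6 in H82 and 89.3 in H524. For H3K4me3 regions it was 72.9 and 29.5. More reads from this part of the chromosome, as extra copies would give, could raise ranks there, which was not tested. Of the 10 highest-scoring H82 regions, 6 were on chromosome 8 and 9 overlapped a NeuroD1 region of H524. Region 1 of the H82 list spanned 128310003 to 128314497 on chromosome 8 (build hg19), was 4.50 kb wide and scored 166. It overlapped the H524 NeuroD1 region from 128310480 to 128313456, which had rank 6 in its list with a score of 250. It overlapped H3K4me3 in both lines, but the mark was high-scoring only in H82. The H82 H3K4me3 region, from 128309413 to 128313182, had rank 3 in its list. The H524 H3K4me3 region, from 128311489 to 128312059, scored 1.38, close to the lowest score of its list. The H82 regions of rank 2 to 4 were at 128657760 to 128659306, 128341853 to 128344442 and 128387301 to 128389664 on the same chromosome, each overlapping H3K4me3 of H82 and a NeuroD1 region of H524. All 10 of the highest-scoring H524 regions were on chromosome 8, and 5 of them overlapped an H82 NeuroD1 region. The highest, from 127416792 to 127426493, was 9.70 kb wide with 13 summits, scored 1048, overlapped H3K4me3 of H524 and had no counterpart in H82. Rank 2 was the region from 128650475 to 128660675, with 19 summits and a score of 587, which overlapped the H82 region of rank 2.

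**Figure D1:**
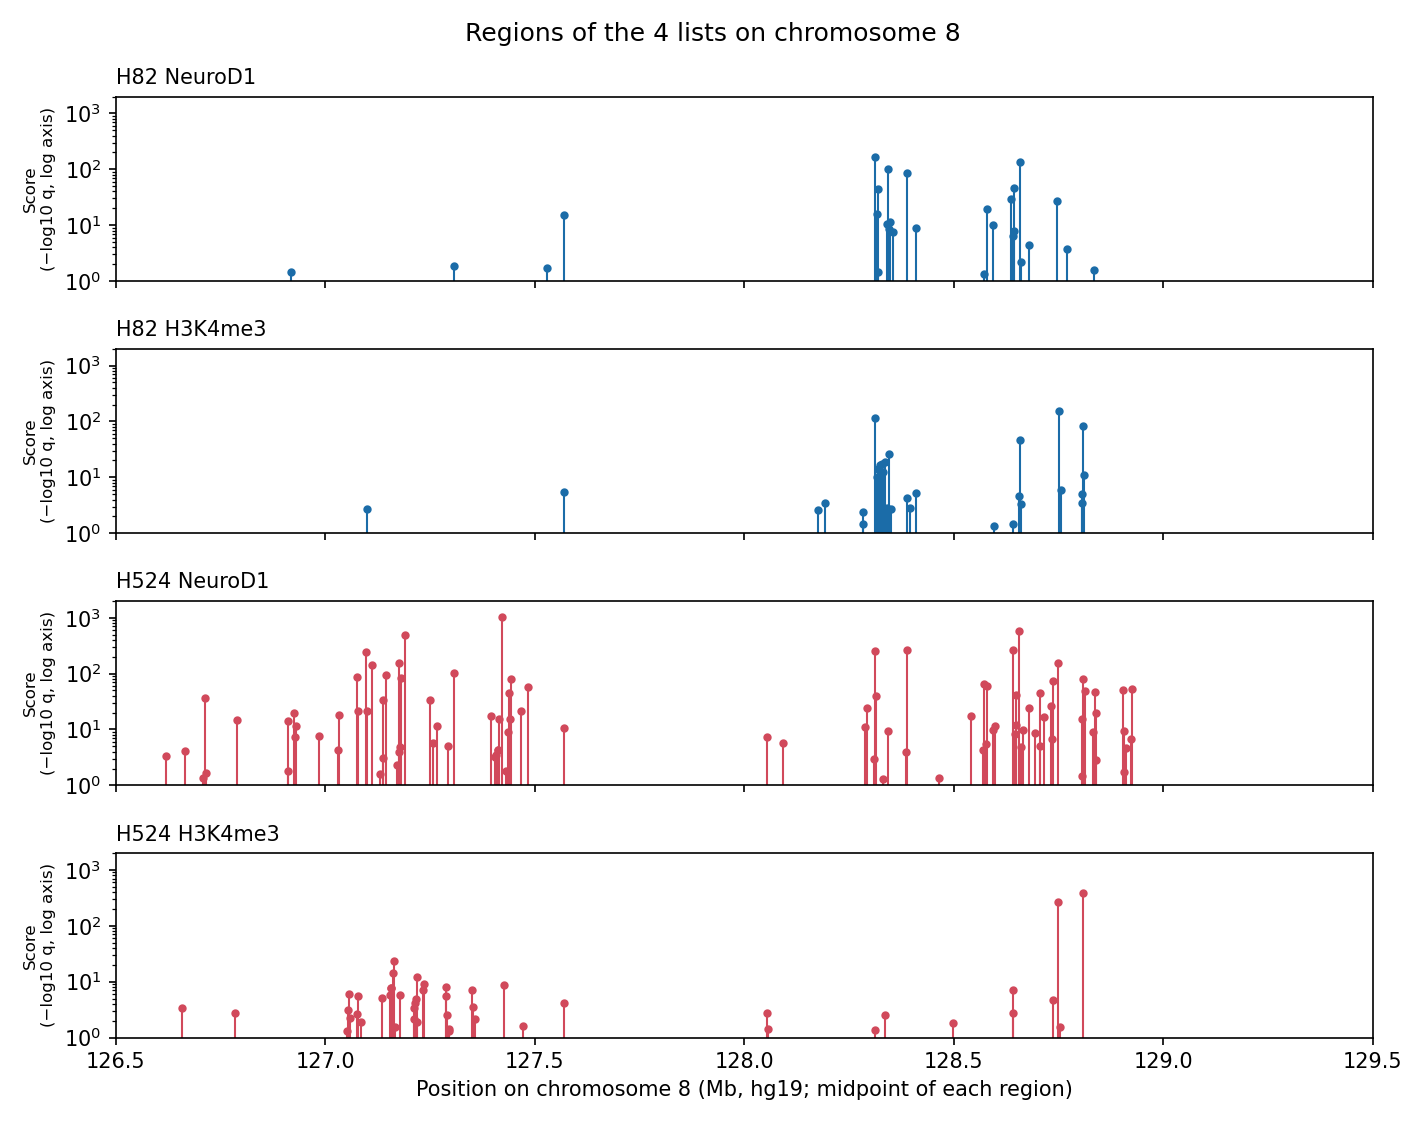
Regions of the 4 lists on chromosome 8 between 126.5 and 129.5 Mb (hg19; horizontal axis, position in Mb; vertical axis, the authors' score on a log scale, 1 panel per list with 1 line per region; scores are not comparable between lists). From 127 to 128 Mb H524 had 37 NeuroD1 and 34 H3K4me3 regions, where H82 had 3 and 2. From 128 to 129 Mb H524 had 49 and 11, and H82 had 24 and 30. Both lines have high-scoring regions between 128 and 129 Mb.

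Outside this part of chromosome 8, the regions that ranked high in both lines were spread over several chromosomes. The region on chromosome 3 from 195163720 to 195164270 had rank 7 in H82 and overlapped the region of rank 33 in H524. The one on chromosome 15 from 98503496 to 98503936 had rank 8 in H82 and rank 15 in H524. Chromosome 17 held regions at 79818252 to 79819013 (ranks 13 and 48) and at 74260981 to 74261390 (ranks 19 and 51). On chromosome 19, the regions were at 10828091 to 10828831 (ranks 16 and 13) and at 14317620 to 14318726 (ranks 11 and 78). Only the first of the chromosome 17 regions overlapped H3K4me3 of its own line in H82, and the regions on chromosomes 3 and 15 lay 0.068 and 0.251 kb from such a region.

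NeuroD1 regions listed in a single line also included high ranks. In H82 the highest of these was at 97901837 to 97903250 on chromosome 8, with rank 6 and a score of 62.6. It was followed by 128317870 to 128319415 on chromosome 8 (rank 12), 195441518 to 195442466 on chromosome 3 (rank 45), 36452850 to 36453183 on chromosome 17 (rank 83) and 201264536 to 201264822 on chromosome 1 (rank 87). In H524 the 5 highest were all on chromosome 8 between 127094675 and 127426493, with ranks 1, 3, 7, 8 and 10. Both lists contained more shared regions among their high scores. With each list divided by score into 10 classes of near-equal size, the share found in the other line was 81.1% (76.8 to 84.9) in the highest class of H82 and 39.2% (34.3 to 44.3) in the lowest. In H524 the corresponding shares were 25.9% (24.0 to 27.9) and 3.25% (2.53 to 4.11).

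H3K4me3 gave a reference for how far the lines overlapped under one antibody. H82 had 9535 of its 18208 H3K4me3 regions in H524 (52.4%, 51.6 to 53.1), and H524 had 9845 of its 18595 regions in H82 (52.9%, 52.2 to 53.7). Random placement of the H82 regions gave 1.11%, so the observed share was 47.1-fold higher, and it was 26.7-fold higher than after moving the regions by 20 to 200 kb. H3K4me3 regions found in both lines had a median width of 803 bp in H82 and 699 bp in H524, against 412 bp and 399 bp for those of a single line. Allowing a distance of up to 1 kb between regions raised the shared part to 67.7% in H82 and 63.2% in H524. The H3K4me3 lists were close in length and the NeuroD1 lists were not, so their whole-list shares are not directly comparable. With each pair cut to equal length, 52.1% of 18208 H82 H3K4me3 regions were shared, against 22.1% of 3854 H82 NeuroD1 regions.

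Wide H3K4me3 regions with high scores in both lines were found on chromosome 8, where an effect of extra copies on ranks was not tested. The region from 128746175 to 128754838 had rank 2 in H82, with 20 summits over 8.66 kb, and its counterpart from 128746165 to 128753376 had rank 2 in H524. The highest-scoring H524 region, from 128805090 to 128812396, overlapped the H82 region of rank 7. Many of the other high ranks were narrow regions beside the longest stretch of a chromosome without any region. Among the 25 highest-scoring H3K4me3 regions, 15 in H82 and 10 in H524 lay within 2 Mb of such a stretch, against 1 and 0 of the 25 highest-scoring NeuroD1 regions. They included most of the highest-scoring H3K4me3 regions of a single line, namely 46403405 to 46403890 on chromosome 16 and 42386962 to 42387404, 42596874 to 42597185 and 42395936 to 42396244 on chromosome 10 in H82. In H524 they were 9827066 to 9827555 on chromosome 21 and 61712441 to 61712759, 61719461 to 61719882 and 61710996 to 61711393 on chromosome X. The remaining region by this rule was at 128657288 to 128660152 on chromosome 8 in H82 and at 228770941 to 228771669 on chromosome 1 in H524, and each overlapped NeuroD1 of its own line.

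Away from those stretches, a choice made after the lists had been seen, the highest H3K4me3 regions of H82 alone included 60190023 to 60195903 on chromosome 14, 128342247 to 128350925 on chromosome 8 and 101031895 to 101040959 on chromosome 3. The first and second of these overlapped a NeuroD1 region in each line. For H524 alone they included 127162630 to 127165804 on chromosome 8, 78441730 to 78442602 on chromosome 15 and 45234993 to 45236108 on chromosome 2, the last of which overlapped NeuroD1 of H524.

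The pairing of both antibodies in each line allowed the share of NeuroD1 regions at the promoter mark to be measured. A minority of NeuroD1 regions overlapped H3K4me3 of the same line, with a larger share in H82. The overlap was 1132 of 3854 regions in H82 (29.4%, 27.9 to 30.8) and 3301 of 20593 in H524 (16.0%, 15.5 to 16.5), a difference of 13.3 percentage points (Newcombe 95% interval 11.8 to 14.9). Random placement gave 1.003% in H82 and 0.953% in H524, 29.3-fold and 16.8-fold below the observed shares. The observed share was 15.3-fold and 12.0-fold higher than after moving the regions by 20 to 200 kb. From the side of the mark, 6.34% (5.99 to 6.71) of the H82 and 18.0% (17.5 to 18.6) of the H524 H3K4me3 regions overlapped NeuroD1 of the same line.

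The difference between the lines depended on which lists were shortened. Limiting the H524 NeuroD1 list to its 3854 highest-scoring regions, an alternative added after the data had been seen, gave an overlap of 472 regions (12.2%, 11.2 to 13.3) and a difference of 17.1 points. Limiting in each line the longer of the NeuroD1 and H3K4me3 lists to the length of the shorter, as planned, gave 14.4% in H82 and 15.9% in H524, and the difference became −1.52 points. This limit left 3854 of the 18208 H3K4me3 regions in H82 and all 18595 in H524.

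**Figure D2:**
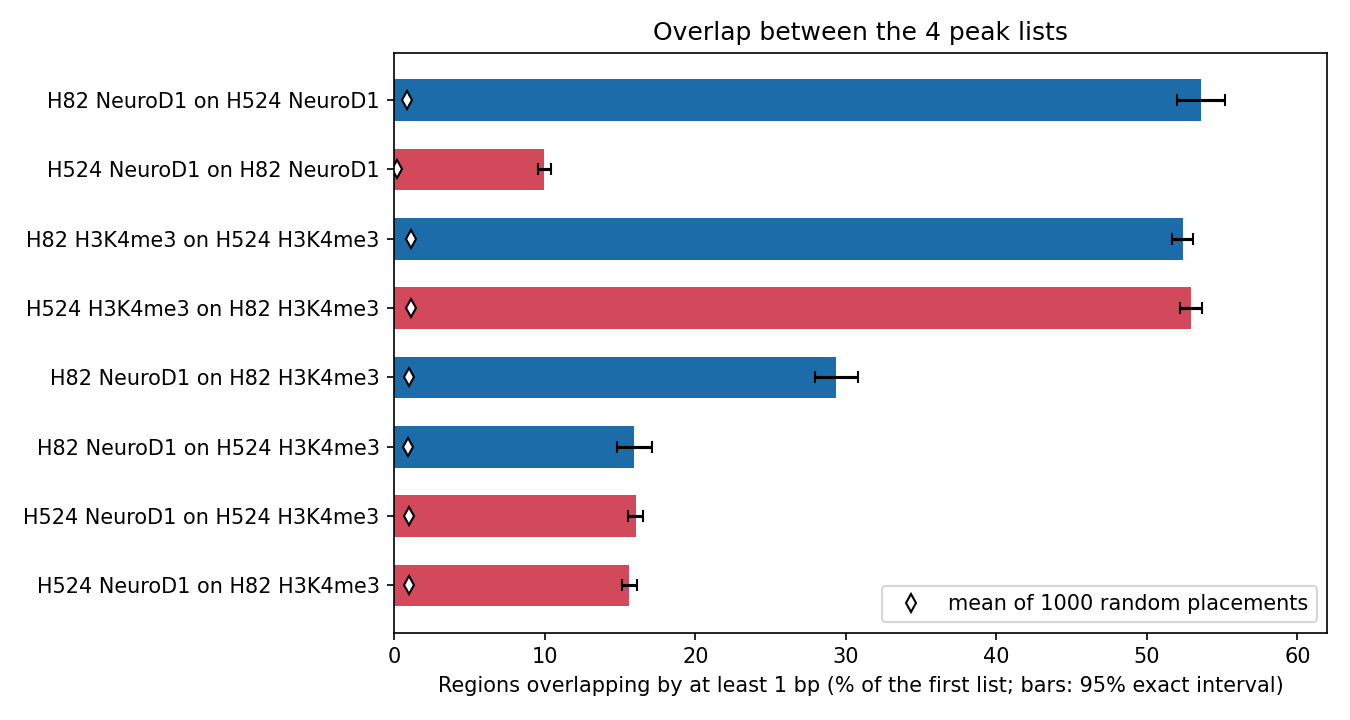
Share of regions of a list (horizontal axis, percent) that overlapped another list by at least 1 bp, for NeuroD1 and H3K4me3 between the lines and for NeuroD1 on H3K4me3 of its own and of the other line (vertical axis; blue, H82; red, H524). Bars are single-library shares with exact 95% intervals for counting error, and diamonds are the mean of 1000 random placements; NeuroD1 sharing is 53.6% from H82 and 9.98% from H524.

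NeuroD1 regions of H82 overlapped the mark of H82 more often than that of H524 (29.4% against 15.9%, 14.8 to 17.1). For H524 regions, the shares on the mark of H524 and of H82 were close (16.0% against 15.6%, 15.1 to 16.1). In H82, 605 NeuroD1 regions (15.7%) carried the mark in H82 alone and 86 (2.23%) in H524 alone, while 2636 (68.4%) carried it in neither line. The corresponding numbers for H524 regions were 993 (4.82%) with the mark in H524 alone, 908 (4.41%) with the mark in H82 alone and 16384 (79.6%) with the mark in neither. Most NeuroD1 regions were therefore outside listed H3K4me3. Among these, the median distance to the nearest H3K4me3 region of the same line was 37.5 kb in H82 and 60.4 kb in H524. Over all regions, overlapping ones included, the median distance to H3K4me3 of the same line was 10.6 kb in H82 and 40.4 kb in H524. In H82 31.6% and in H524 45.7% of all NeuroD1 regions lay over 50 kb away, against 68.5% and 66.0% of randomly placed regions.

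NeuroD1 regions shared by the lines overlapped H3K4me3 more often than those of a single line. In H82, 33.5% (31.5 to 35.6) of the 2066 shared regions and 24.6% (22.6 to 26.6) of the 1788 others overlapped H3K4me3 of H82, a difference of 8.99 points (6.13 to 11.8). In H524 the shares were 26.2% (24.3 to 28.1) of 2055 and 14.9% (14.4 to 15.4) of 18538, a difference of 11.3 points (9.35 to 13.3). These 2 differences were not adjusted for score, with which sharing and overlap both varied. The H82 difference was 5.51 points when all lists involved were limited to regions at or above their median score, and it was 15.7 points when regions within 1 kb counted as shared and as overlapping. Conversely, H3K4me3 regions found in both lines overlapped NeuroD1 of H524 more often than those of H524 alone (25.3%, 24.5 to 26.2, against 9.85%, 9.23 to 10.5). For H82 the shares were 7.36% (6.85 to 7.90) and 5.22% (4.76 to 5.71). H3K4me3 regions found in both lines were also wider, and wider ones overlapped NeuroD1 more often. The 2 contrasts between H3K4me3 regions were not adjusted for width, so how far width accounts for each was not determined.

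The NeuroD1 regions with the highest scores overlapped the promoter mark most often in H82 and least often in H524. In H82, 45.6% (40.5 to 50.7) of the highest-scoring of 10 classes and 25.2% (20.9 to 29.8) of the lowest overlapped H3K4me3. The H82 difference rested on the highest class, as classes 2 to 10 lay between 25.2% and 30.1%. In H524 the highest class had 12.1% (10.8 to 13.6) and the lowest 16.6% (15.0 to 18.2), with 12.1% to 13.7% in classes 1 to 3 and 16.6% to 17.9% in classes 4 to 10. With 4 classes in place of 10, the difference between the highest and lowest class was 9.52 points in H82 and −4.06 points in H524.

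**Figure D3:**
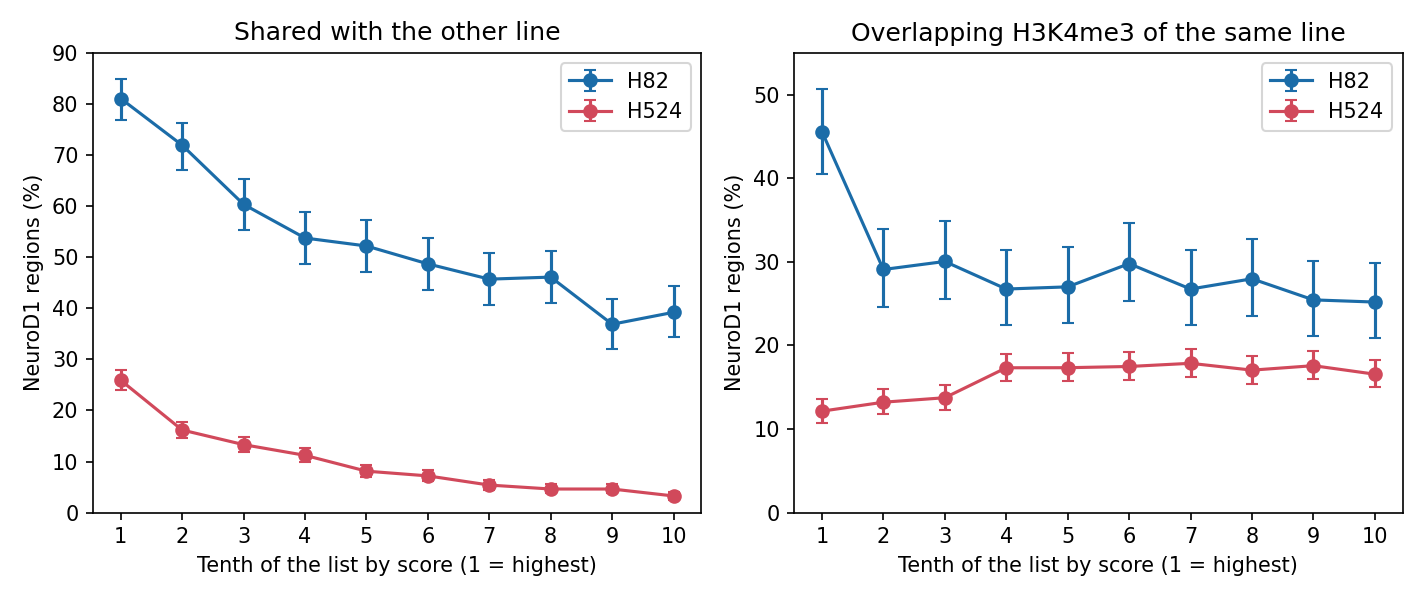
Share of NeuroD1 regions (vertical axis, percent) found in the other line and overlapping H3K4me3 of the same line, by class of the list's own score from 1 (highest) to 10 (lowest), for H82 and H524, with exact 95% intervals for counting error. Sharing with the other line falls from 81.1% to 39.2% in H82 and from 25.9% to 3.25% in H524, while overlap with H3K4me3 is 45.6% in class 1 and 25.2% to 30.1% in the other classes of H82 and goes from 12.1% to 16.6% in H524.

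The distribution of regions over the chromosomes differed between the lines, mostly alike under both antibodies. Chromosome 10 held 1.79% (1.40 to 2.26) of the H82 NeuroD1 regions and 0.685% (0.577 to 0.807) of those of H524, and 3.02% (2.78 to 3.28) and 0.774% (0.653 to 0.911) of the H3K4me3 regions. The H524 share was thus 2.61-fold lower for NeuroD1 and 3.90-fold lower for H3K4me3. Chromosome 22 was higher in H524 under both antibodies, 2.51-fold for NeuroD1 and 1.58-fold for H3K4me3, and chromosome 1 was 1.69-fold and 1.41-fold lower. Chromosomes 4 and 19 went opposite ways under the antibodies. The share of chromosome 4 was 1.14-fold higher in H524 for NeuroD1, with overlapping intervals (1.74 to 2.69 against 2.27 to 2.70%), and 1.32-fold lower for H3K4me3. Chromosome 19 differed beyond the intervals under both, with 4.90% (4.24 to 5.63) of the NeuroD1 regions in H82 and 3.20% (2.96 to 3.45) in H524, but 5.77% (5.43 to 6.12) and 10.3% (9.90 to 10.8) of the H3K4me3 regions. The 1343 H524 H3K4me3 regions of chromosome 19 without a counterpart in H82 had a median percentile of 29.0 by score in their list and a median width of 385 bp, against 69.8 and 681 bp for the 578 with one.

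**Figure D4:**
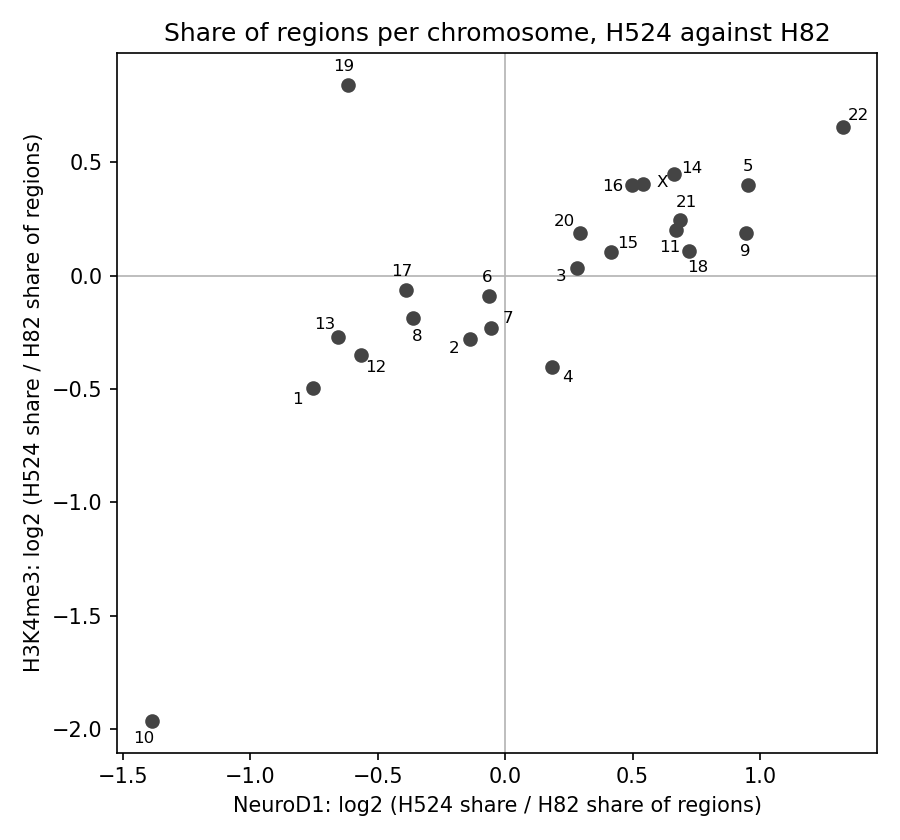
Log2 of the H524 over the H82 share of regions for each of 23 chromosomes, NeuroD1 on the horizontal and H3K4me3 on the vertical axis, 1 labelled point per chromosome. Chromosome 10 is lowest on both axes (−1.39 and −1.96), and chromosome 19 stands apart with −0.62 and 0.84.

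Across the 23 chromosomes, which are not independent replicates, the log2 ratios of both antibodies had a Pearson r of 0.702 and a Spearman rho of 0.679. Without chromosome 19 these were 0.859 and 0.851, without chromosome 10 they were 0.577 and 0.633, and without both they were 0.868 and 0.829.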

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

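The tests on chromosome 19 below were chosen before their results were seen, after the chromosome shares were known.

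Chromosome 19 stood out because the log2 ratio of the H524 to the H82 share of regions went opposite ways with separate counting intervals under both antibodies, −0.62 for NeuroD1 and 0.84 for H3K4me3, 1.46 apart, a difference that was not tested. The excess of H3K4me3 regions in H524 was 1.79-fold over the whole lists and was not limited to weak regions near the calling threshold. Among H3K4me3 regions at or above the median score of their list, it was lower but still 1.42-fold (95% interval 1.28 to 1.58). Regions beside the longest empty stretch of the chromosome did not account for it either, with a 1.79-fold higher share (1.66 to 1.92) without them. More copies of chromosome 19 in H524 could not be told apart from other explanations, because the share of NeuroD1 regions over 1 kb from H3K4me3 was 1.14-fold higher with an interval of 0.827 to 1.56. A difference between the lines in promoter marking on this chromosome may also contribute and was not tested.

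The relation of NeuroD1 score to H3K4me3 was listed because the difference between the highest and the lowest score class had opposite signs in the lines. The highest minus the lowest of 10 score classes was 20.4 percentage points in H82 and −4.43 points in H524, 24.8 points apart, a difference that was not tested between libraries. In H82 it rested on the highest class, at 45.6%, since classes 2 to 10 lay between 25.2% and 30.1%.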

How the results depend on the processing

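Alternatives that left out regions beside the longest empty stretches or on chromosome 8 from 127 to 129 Mb, counted every summit, shortened only the H524 NeuroD1 list or moved regions by 20 to 200 kb were chosen after the data had been seen. Of 74 alternative values, 33 stayed within the counting interval of the reported value, 40 moved and 1 reversed. The 33 include values from filters that removed few or no regions, described below. The 40 include 4 folds over random placement, which have no interval. The reversal was the H82 minus H524 difference in NeuroD1 overlap with H3K4me3, at −1.52 points with lists of equal length, where the H82 H3K4me3 list was shortened and the H524 one was not. Shortening only the H524 NeuroD1 list gave 17.1 points. In the following, NeuroD1 shared, H3K4me3 shared and NeuroD1 on H3K4me3 are each given for H82, then H524. Requiring overlap of at least 50% of the shorter region gave 50.2% and 9.34%, 46.4% and 47.4%, and 21.9% and 11.9%, with a line difference of 10.1 points. Allowing 1 kb gave 58.5% and 11.6%, 67.7% and 63.2%, and 38.9% and 21.2%, with a line difference of 17.7 points and shared minus single-line differences of 15.7 and 16.8 points. Windows of 200 bp around the midpoint gave 37.1% and 6.95% for NeuroD1 shared and 24.4% and 12.8% on H3K4me3, with a line difference of 11.6 points. These moves follow from looser or stricter overlap. Limiting both lists of each overlap to scores at or above their medians moved H524 NeuroD1 shared to 9.30%, H82 H3K4me3 shared to 49.9%, NeuroD1 on H3K4me3 to 25.1% and 11.1%, and the H82 shared minus single-line difference to 5.51 points. Fewer regions were then left to overlap with, and the cause of the change in the difference was not tested. Lists of equal length gave 22.1% and 21.7% for NeuroD1 shared and 14.4% for H82 NeuroD1 on H3K4me3. The H82 values fell with fewer regions to overlap with, and the H524 value rose as only its highest-scoring regions stayed, which were shared more often. Counting every summit gave 11.7% for H524 NeuroD1 shared and 62.1% and 60.4% for H3K4me3 shared, as regions with several summits weigh more. With 4 score classes, highest minus lowest was 33.9 and 15.8 points for sharing and 9.52 points for H82 overlap with H3K4me3, as the end classes are broader. After moves of 20 to 200 kb the folds were 33.1 and 26.7 for H82 NeuroD1 and H3K4me3 sharing, and 15.3 and 12.0 for NeuroD1 on H3K4me3 in H82 and H524. Using only chromosomes 1 to 22 and X, or leaving out the chromosome 8 regions or those beside empty stretches, kept the 6 shares of whole lists and the line difference within their intervals. Score classes and shared against single-line regions were not recomputed without those regions, nor were chromosome shares, except that of chromosome 19 under H3K4me3 without regions beside empty stretches (1.79-fold).

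Alternatives for genomic annotation, genes with NeuroD1 or H3K4me3, gene lists and E-box content had been planned and were not run, since an hg19 genome and annotation were not used here. No paired analysis was possible because each line had 1 library per antibody. Unknown depth limits the comparison of list lengths, above all the 5.34-fold difference in NeuroD1 regions.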

Other observations

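The tests of the missing stretch on chromosome 10 and of chromosome 8 below, and the comparison with H82 percentiles on chromosome 10, were chosen after the results had been seen.

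Wide H3K4me3 regions carried NeuroD1 more often than narrow ones in both lines. With H3K4me3 regions divided by width into 5 classes, the share overlapping NeuroD1 of the same line was 2.91% in the narrowest and 13.0% in the widest class in H82, and 7.66% and 35.8% in H524. A wider region also meets more randomly placed ones, but the fold over random placement was higher in the widest class as well, 30.6 against 23.5 in H82 and 19.9 against 10.6 in H524. The share found in the other line went from 25.2% to 84.1% in H82 and from 27.7% to 82.3% in H524.

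Blocks of 1 Mb differed in how many regions they held in each line. The H524 NeuroD1 list was 5.34-fold longer in total, and beside this chromosome 16 from 85 to 86 Mb held 96 NeuroD1 regions in H524 and 10 in H82, and chromosome 20 from 20 to 21 Mb held 56 and 3. The densest NeuroD1 block of H82, chromosome 14 from 57 to 58 Mb, held 29 regions there and 32 in H524. Under H3K4me3, chromosome 6 from 27 to 28 Mb held 100 regions in H82 and 71 in H524, chromosome 17 from 7 to 8 Mb held 73 and 6, and chromosome 19 from 37 to 38 Mb held 37 and 117.

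On chromosome 8 from 127 to 128 Mb, H524 had 37 NeuroD1 and 34 H3K4me3 regions where H82 had 3 and 2, beside whole-list ratios of 5.34 for NeuroD1 and 1.02 for H3K4me3, whereas from 128 to 129 Mb H3K4me3 had 11 regions in H524 and 30 in H82. The difference was not limited to NeuroD1, as H3K4me3 regions were also more frequent, with an H524 over H82 ratio of 11.7 after adding 1 to each count. Of the 34 regions, 5 overlapped NeuroD1 (14.7%, 4.95 to 31.1), beside 18.0% of all H524 H3K4me3 regions. The ratio of 11.7 was at percentile 99.9 of 2515 blocks, but it restates the counts by which the block was noticed. It therefore excludes no cause. A gain of NeuroD1 binding, and more reads from the block in H524, as extra copies would give, remain untested. Both lines are known to carry amplified MYC, a gene of chromosome 8 whose position was not looked up here. Extra copies could also bear on the high ranks of both lines from 128 to 129 Mb, which was not tested. A change of chromatin state across the block in H524 would raise both antibodies too and was not tested either, and the input libraries, which would help to separate these, were not analysed here.

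Chromosome 10 held a 3.90-fold lower share of H3K4me3 and a 2.61-fold lower share of NeuroD1 regions in H524 than in H82. Of 12 blocks of 10 Mb with 10 or more H3K4me3 regions in H82, 0 were empty in both H524 lists. A missing stretch that filled such a block was therefore not seen. Shorter stretches, or those across the edge of a block, cannot be excluded this way. Fewer copies of the chromosome in H524 could lower scores as well as counts, and the sign set for this beforehand, a median percentile under 50 under both antibodies, was met in H524 with 31.7 (25.8 to 33.2) for H3K4me3 and 46.8 (36.5 to 48.0) for NeuroD1. The medians of H82 were also under 50, at 47.5 and 46.4, so a comparison with H82 was added after these values were seen, and it overturned the reading in favour of fewer copies. H524 was below H82 for H3K4me3 but not for NeuroD1, so fewer copies cannot be told apart from other differences between the lines.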
